A study of Sus scrofa with 6 samples.

How the data were processed

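Total RNA from the longissimus dorsi, the long back muscle, of 25-day-old male piglets was hybridised to Affymetrix porcine arrays, 1 array per animal. Of the 6 animals, 3 were Yorkshire, a lean breed used widely in commercial pig production, and 3 were Shaziling, an indigenous Chinese breed. Per the labels' protocols, the 3 animals of each breed were full siblings, and each breed came from its own farm. Breed, litter and farm therefore cannot be told apart in any comparison given here, and the p-values measure the spread between siblings, not between unrelated animals of a breed.

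The signals were made with MAS5, per the submitters' processing notes; its version is not given in the sources used here. MAS5 reduces the perfect-match and mismatch probes of a probe set to 1 signal and gives each signal a detection call. The values deposited by the authors are log2 MAS5 signals, with a lowest value of 0, and each array has a 2% trimmed mean close to 500 on the linear scale (500.1 to 500.2), so the arrays had been scaled to one another before deposit. The deposited calls are Present, Marginal or Absent for each probe set and array, per the file headers. The 2 deposited tables held the same log2 signals, with 0 differing values, and the one that also carried calls and annotation was used. The file's annotation dates from June of an earlier decade, and its symbols were brought up to date through the Entrez gene IDs and a RefSeq gene table of the Sscrofa11.1 assembly, which was used for names alone. Of 23999 non-control probe sets, 9034 had exactly 1 named gene, covering 6391 genes. A further 12443 had no gene in the file, 2089 had only a placeholder name, 332 listed several genes, and for 101 the file's symbol and the current gene of its ID differed; none of these was given a gene name. Chromosome positions are those of the file, which does not give its assembly version in a readable form.

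The arrays held 24123 probe sets, of which 124 were AFFX controls and were left out of the tests. Probe sets with a Present call on at least 3 of the 6 arrays, whatever the breed, were tested, which left 14413, of which 5901 had 1 named gene (4612 genes). No further normalization and no offset were applied. The breeds were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend=TRUE), as Shaziling minus Yorkshire, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of adjusted p under 0.05 without a fold limit. All adjusted p-values of probe sets come from this limma model. Fold changes are on the log2 scale with the model's moderated SE, and intervals are 95% intervals from the same model. A probe set without a Present call on any array of a breed has only a bound in that breed, and its fold is given as "at least". The bound sets the mean of the other breed against, per array, the higher of the lowest Present signal and the probe set's own signal. Past the threshold it equalled the fold of the deposited signals, and it takes no account of the 95% interval, which reaches smaller folds.

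Gene lists for muscle fibres, metabolism, growth, stress, immunity and the other cell types that a piece of muscle can hold were written before the data were examined. Of 43 lists, 33 had at least 5 tested genes and were compared by limma's camera with its preset correlation of 0.01, on 1 probe set per gene (the one of highest mean signal), with Benjamini-Hochberg adjustment over the 33 lists. Each list was tested again with the correlation estimated from the data and with fry, which asks only whether a list's genes move on balance in one direction. The median of each list was also set against 10000 random lists matched on mean signal in 20 bins.

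Genes named in the text were chosen by a rule set before the data were examined. They are, to begin with, up to 12 genes per direction with the largest fold change among probe sets past the threshold that had 1 real gene symbol and did not overlap between breeds; next, up to 4 genes of smallest p in each list described; then IGF2, MSTN, PRKAG3, RYR1, CAST, FABP3, FABP4, GHR, IGF1, MYH4 and MYH7, known from pig growth, meat quality or fibre type, whatever their result; and finally the control probe sets. Any other gene or probe set that is named was chosen after its values were seen, and this is said where it is named.

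The procedure was checked on simulated data built on 14413 probe sets with the signal levels and spread of these arrays, with 200 changed probe sets in each of 10 runs. It recovered 27.2% of probe sets changed by 1 on the log2 scale, 88.6% of those changed by 2, 97.4% of those changed by 3 and 99.2% of those changed by 4. Of the calls, 7.13% were unchanged probe sets, and with nothing changed there were on average 0.3 calls per run. A ribosomal list shifted by 0.3 was called in 10 of 10 runs, and with nothing changed 0.2 lists were called per run on average. The simulated genes were independent, with normal noise, so the list results do not cover lists whose genes vary together. The rates for single probe sets likewise leave out variation that many probe sets of an array share. They hold for 200 changed probe sets, and with fewer changed the adjustment is stricter and recovery may be lower. Changes near 2-fold or smaller in single genes were thus mostly out of reach with 3 arrays per breed, whose number limits the precision of every value.

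Alternatives covered the normalization (quantile, equal medians, cyclic loess), the filter on dim probe sets, an offset of 16 or 64 before log2, the variance model, array weights, probe sets open to cross-hybridisation, the threshold, leaving out each array, and for the lists the test, the correlation and the mean over a gene's probe sets. A fit with each array's percent of Present calls as a covariate was added after seeing the data, as were tests of the Gene Ontology terms in the file's annotation. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.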

Results

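Gene expression in the longissimus dorsi was compared between 3 Yorkshire and 3 Shaziling male piglets of 25 days. Present calls covered 59.9%, 58.2% and 60.6% of probe sets on the Yorkshire arrays and 59.9%, 56.3% and 58.1% on the Shaziling arrays, a difference between breeds within the spread of the arrays (exact permutation p = 0.3). With 3 arrays against 3 such a p cannot be below 0.1. Of 23999 non-control probe sets, 11504 were Present on all 6 arrays and 6902 on none. Pearson correlations across tested probe sets ranged from 0.934 to 0.962 within Yorkshire, from 0.943 to 0.960 within Shaziling and from 0.924 to 0.957 between breeds. The difference between 3' and 5' signals was 4.97 ± 0.14 for actin in Yorkshire and 4.46 ± 0.46 in Shaziling (log2, SD, n = 3; exact permutation p = 0.3), and 0.07 ± 0.04 against 0.08 ± 0.13 for GAPDH (exact permutation p = 0.9). The mean of the hybridisation control spike-ins was 12.09 ± 0.12 in Yorkshire and 12.25 ± 0.17 in Shaziling (log2, SD, n = 3). For the poly-A control spike-ins it was 8.86 ± 0.15 against 9.09 ± 0.18 (exact permutation p = 0.2). The 28S ribosomal RNA probe set had 13.77 ± 0.38 against 14.18 ± 0.34 (exact permutation p = 0.3).

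Muscle of the Shaziling piglets differed from that of the Yorkshire piglets in the mRNA signal of a small set of genes, in both directions, with changes from 2.05-fold to at least 11.5-fold. Signals fell in Shaziling for RNF157, a RING finger protein of the ubiquitin ligase type, for TMSB15B, an actin-binding thymosin, and for HUS1, a subunit of the DNA damage checkpoint clamp. They fell for EPHX2, the soluble epoxide hydrolase that breaks down fatty acid epoxides. They also fell for DPP4, a cell surface peptidase that cleaves incretin hormones. Those of the mitochondrial proteins MARC2, a molybdenum-containing reductase, and SFXN4, a sideroflexin of the inner membrane, fell as well. Signals rose for NEK3, a NIMA-related kinase, LYZ, the lysozyme of macrophages and neutrophils, and ACOX3, a peroxisomal oxidase of branched-chain fatty acids. They rose for single probe sets of EEA1, an early endosome tether, and MARCH6, a ubiquitin ligase of the endoplasmic reticulum. In total 31 of 14413 probe sets passed the threshold in the limma model, 14 higher and 17 lower in Shaziling, of which 12 had a named gene and 19 had none.

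HUS1 had the smallest adjusted p: its log2 signal was 10.22 ± 0.33 in Yorkshire and 7.58 ± 0.24 in Shaziling (SD, n = 3), a fall of 6.24-fold (log2 fold change -2.64, SE 0.25, limma adjusted p = 0.0139). EPHX2 went from 10.14 ± 0.31 to 7.80 ± 0.54, or 5.04-fold (log2 fold change -2.33, SE 0.31, limma adjusted p = 0.0255). MARC2 was the brightest of the genes that fell, at 12.67 ± 0.38 in Yorkshire and 10.82 ± 0.22 in Shaziling, 3.60-fold (log2 fold change -1.85, SE 0.22, limma adjusted p = 0.0199). DPP4 had a log2 fold change of -2.01 (SE 0.29) and SFXN4 of -1.60 (SE 0.23), both with a limma adjusted p of 0.0425. RNF157 was Present on all Yorkshire arrays and on no Shaziling array and was at least 9.94-fold lower in Shaziling (8.08 ± 0.39 against 4.76 ± 0.91; limma adjusted p = 0.0406). TMSB15B, Present on 3 Yorkshire arrays and 1 Shaziling array, had a log2 fold change of -3.02 (SE 0.45, limma adjusted p = 0.0425).

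Among the genes that rose, NEK3 went from 7.21 ± 0.38 in Yorkshire to 9.53 ± 0.29 in Shaziling (SD, n = 3), or 4.97-fold (log2 fold change 2.31, SE 0.27, limma adjusted p = 0.0181). LYZ went from 6.60 ± 0.36 to 8.66 ± 0.39, or 4.15-fold (log2 fold change 2.05, SE 0.30, limma adjusted p = 0.0425). ACOX3 had a log2 fold change of 1.71 (SE 0.26, limma adjusted p = 0.0425), with a Present call on 1 Yorkshire array and 2 Shaziling arrays. The EEA1 probe set was Present on no Yorkshire array and was at least 7.55-fold higher in Shaziling (limma adjusted p = 0.0425), while the 3 other EEA1 probe sets had log2 fold changes of -0.07, -0.20 and -0.21 and did not pass. The MARCH6 probe set had a log2 fold change of 1.72 (SE 0.20, limma adjusted p = 0.0176), while the 3 other MARCH6 probe sets had 0.21, -0.24 and -0.28 and did not pass. With the mean over all probe sets of a gene, the log2 fold change was 0.61 for EEA1 (limma adjusted p = 0.511, over a range of 0.00417 to 0.511 among its alternatives) and 0.35 for MARCH6 (limma adjusted p = 0.642, over a range of 0.00197 to 0.642).

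In the file's coordinates, EPHX2 lies on chromosome 14 from 11336348 to 11412299, SFXN4 on chromosome 14 from 135033765 to 135049555, DPP4 on chromosome 15 from 63908120 to 63990643 and LYZ on chromosome 5 from 32494727 to 32501046. The NEK3 probe set was placed on chromosome 11 from 15817038 to 15817563 and the MARCH6 probe set on chromosome 16 from 69470364 to 69471159. The file's alignment of the EEA1 probe set had an identity of 76.0%, that of RNF157 79.4% and that of MARC2 79.9%. It was 94.9% for EPHX2 and 97.9% for SFXN4. Which gene the EEA1, RNF157 and MARC2 probe sets measure is therefore less certain. The HUS1 probe set had no position in the file.

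Some of the probe sets past the threshold without a gene name under the rule had a title, and these were picked after their values were seen. A probe set titled as similar to SATB1, a chromatin organiser, had a log2 fold change of 1.70 (SE 0.25, limma adjusted p = 0.0425). One titled as similar to YIPF6, a Golgi membrane protein, had 2.07 (SE 0.23, limma adjusted p = 0.0176). One titled as similar to mitochondrial isobutyryl-CoA dehydrogenase, an enzyme of valine breakdown, had -1.89 (SE 0.28, limma adjusted p = 0.0425). The largest change past the threshold, at least 11.5-fold lower in Shaziling, belonged to a probe set with neither gene nor title, placed on chromosome 13 from 32586948 to 32587502.

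All 31 probe sets were separated by breed, with the 3 signals of one breed above the 3 of the other, as were 16.3% of all tested probe sets, against 10% by chance for 3 against 3. At an unadjusted p under 0.05 there were 1499 probe sets, 631 higher and 868 lower in Shaziling, where chance gives 721 for independent probe sets. The splits of the 6 arrays into 3 and 3 that cut across breed gave 189 to 1909, so 1499 is within reach of another grouping. No probe set passed in limma without Yorkshire replicate 1 (1020 at an unadjusted p under 0.05) or without Shaziling replicate 6 (1096). In the other fits 11 passed without Yorkshire replicate 2, 5 without Shaziling replicate 5, 24 without Yorkshire replicate 3 and 27 without Shaziling replicate 4. Over these 6 fits the log2 fold change lay from -2.79 to -2.47 for HUS1, from 2.17 to 2.53 for NEK3 and from -2.06 to -1.71 for MARC2. As all 31 were separated by breed, leaving out 1 array could not change their signs.

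**Figure D1:**
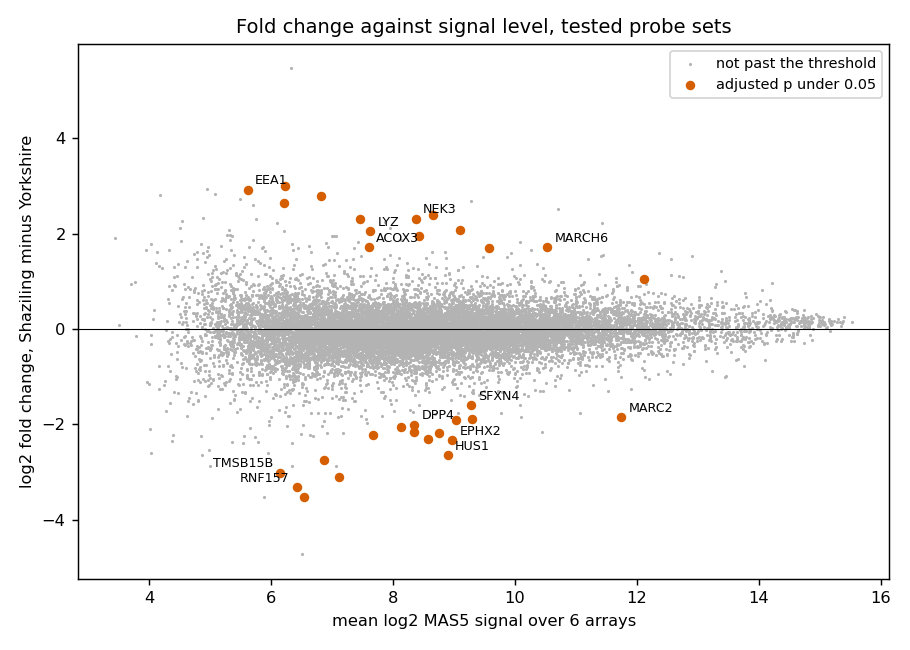
Each point is 1 of the 14413 tested probe sets, with its mean log2 MAS5 signal over the 6 arrays on the x axis and its log2 fold change (Shaziling minus Yorkshire) on the y axis. The 31 probe sets past the threshold, in orange with the 12 named genes labelled, range from 2.05-fold to at least 11.5-fold, and those without a Present call in a breed are drawn at their deposited signals.

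**Figure D2:**
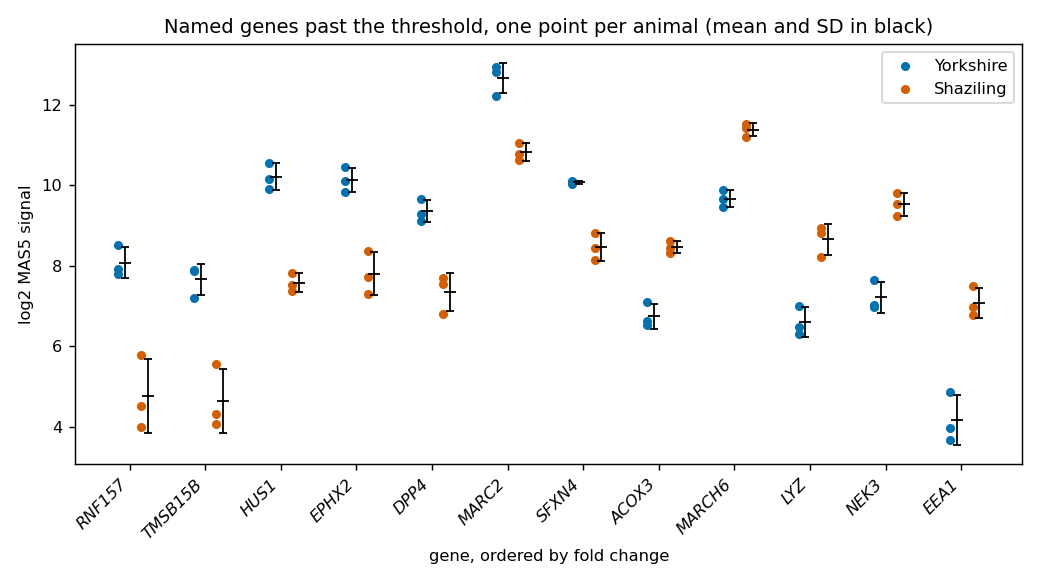
Log2 MAS5 signal (y axis) of the 12 named genes past the threshold (x axis, ordered by the difference of the means), 1 point per animal, with the mean and SD of the 3 animals of each breed in black. The Yorkshire and Shaziling points do not overlap for any of the 12 genes, which the rule for naming them required. RNF157 has no Present call in Shaziling and EEA1 none in Yorkshire.

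Genes with known roles in pig growth and meat traits were read whatever their result, and none passed the threshold in limma. MSTN, the inhibitor of muscle growth, had a log2 fold change of 0.95 (SE 0.32, adjusted p = 0.332) and the growth factor IGF1 had -1.08 (SE 0.34, adjusted p = 0.314), each separated by breed. A second MSTN probe set had 0.56 (SE 0.47) and a second IGF1 probe set -0.34 (SE 0.29). Of 12 probe sets of IGF2, an imprinted growth factor, 7 were Present on no array and 2 were tested, with log2 fold changes of -0.35 (SE 0.25, adjusted p = 0.671) and -1.06 (SE 0.36, adjusted p = 0.340). The brightest of 5 probe sets of CAST, the calpain inhibitor linked to tenderness, had 0.60 (SE 0.22, adjusted p = 0.383), and the others had 0.75, 0.37, 0.12 and -0.18. FABP3, the heart-type fatty acid carrier, had -0.47 (SE 0.35) and GHR, the growth hormone receptor, 0.10 (SE 0.48). FABP4, the adipocyte fatty acid carrier, had 0.47 (SE 0.25, adjusted p = 0.552) for its brighter probe set. Its other probe set had 2.52 (SE 0.84, adjusted p = 0.338). RYR1, the calcium release channel in which a variant causes stress susceptibility, had 0.15 (SE 0.18). The fast myosin MYH4 and the slow myosin MYH7 had 0.06 (SE 0.13) and 0.05 (SE 0.11), at log2 signals of 15.32 and 14.94 in Yorkshire, close to the highest signals of the arrays. PRKAG3, the AMPK subunit linked to muscle glycogen, was Present on no array.

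The 3 lists of mitochondrial energy metabolism passed as lower in Shaziling, most stably that of the tricarboxylic acid cycle. Of 13 genes of the tricarboxylic acid cycle, 11 had negative fold changes, with a list median of -0.25 (camera adjusted p = 0.00269; adjusted p = 0.608 with an estimated correlation). None of them passed over all probe sets, and 3 were lower adjusted over the list alone. Its leading members were PDHA1 of pyruvate dehydrogenase (log2 fold change -0.77, SE 0.21), DLST of the oxoglutarate dehydrogenase complex (-0.62, SE 0.19), citrate synthase CS (-0.48, SE 0.15) and IDH3A (-0.59, SE 0.23). Of 19 genes of fatty acid uptake and oxidation, 15 were negative, with a median of -0.42 (camera adjusted p = 0.00658; adjusted p = 0.737 with an estimated correlation), and 0 passed over all probe sets or adjusted over the list alone. They were led by PPARGC1A, the coactivator that drives mitochondrial biogenesis (-0.94, SE 0.24), lipoprotein lipase LPL (-0.61, SE 0.21), ACSL1 (-0.54, SE 0.20) and HADH (-0.46, SE 0.17). Of 20 genes of oxidative phosphorylation, 16 were negative, with a median of -0.19 (camera adjusted p = 0.0236; adjusted p = 0.809 with an estimated correlation), and 0 passed over all probe sets or adjusted over the list alone. Its succinate dehydrogenase genes SDHC (-0.79, SE 0.25), SDHA (-0.53, SE 0.20) and SDHB (-0.31, SE 0.13) stood against COX7C of complex IV, at 0.37 (SE 0.13). A further succinate dehydrogenase gene, SDHD, picked after its values were seen, had -0.05 (SE 0.16). Without Yorkshire replicate 1 the camera adjusted p of the fatty acid list was 0.166 (median -0.29) and that of oxidative phosphorylation 0.202 (median -0.18). Without Shaziling replicate 6 they were 0.0743 (median -0.27) and 0.622 (median -0.12). Without Shaziling replicate 4 they were 0.00113 (median -0.51) and 0.000865 (median -0.29). Over all alternatives they ranged from 1.3e-05 to 0.737 and from 6.4e-05 to 0.809, and that of the tricarboxylic acid cycle from 6.4e-05 to 0.608. The fatty acid genes did not split cleanly by breed, nor did those of oxidative phosphorylation. Both lists instead lay higher in Yorkshire replicates 1 and 3 and Shaziling replicate 4. Mean deviations there were 0.37, 0.23 and 0.11 for the fatty acid list. They were -0.13 in Yorkshire replicate 2 and -0.20 and -0.38 in Shaziling replicates 5 and 6. For oxidative phosphorylation they were 0.19, 0.13 and 0.13 against 0.00, -0.10 and -0.35. That split across breed is described among the other observations. For these lists a lower level in Shaziling cannot be told apart from it. With the percent of Present calls as a covariate, a fit added after seeing the data, the median of the fatty acid list was -0.21 (adjusted p = 0.165) and that of oxidative phosphorylation -0.12 (adjusted p = 0.173), neither past the threshold.

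Lists of sarcomere, fast fibre and myogenic genes passed as higher in Shaziling, with small medians, and that of slow fibre genes did not pass. Against random lists matched on signal, which treat genes as independent, the fast fibre median lay only at percentile 70.2, with a matched median of 0.09. The sarcomere median lay at percentile 100 and the myogenic one at 99.8. All 15 tested genes of the sarcomere and Z-disc had positive fold changes, with a median of 0.32 (camera adjusted p = 0.000121; adjusted p = 0.608 with an estimated correlation), none of them past the threshold over all probe sets and 0 adjusted over the list alone. CRYAB, a small heat shock protein of the Z-disc, had 0.88 (SE 0.31), the thin filament cap TMOD4 0.43 (SE 0.16), alpha-actinin ACTN2 0.37 (SE 0.19) and MYOZ1 0.22 (SE 0.11). The list's median was 0.18 without Yorkshire replicate 2, whose mean deviation of -0.53 stood apart, also 0.18 without Shaziling replicate 5, and 0.13 with array weights, and its adjusted p ranged from 7.7e-06 to 0.608 over all alternatives. All 8 tested fast fibre genes were positive, with a median of 0.13 (camera adjusted p = 0.0236; adjusted p = 0.724 with an estimated correlation), with 0 past the threshold over all probe sets and 0 adjusted over the list alone. They were led by the calcium pump ATP2A1 at 0.46 (SE 0.21) and the troponin TNNT3 at 0.24 (SE 0.14). Under cyclic loess the median of the fast fibre list was -0.02 (adjusted p = 0.929) and under quantile normalization 0.01 (adjusted p = 0.840), so that the sign of its median depended on the scaling. Its adjusted p was 0.189 without Yorkshire replicate 2 (median 0.06) and 0.265 without Shaziling replicate 5 (median 0.07), over a range of 0.00690 to 0.929 among all alternatives. The 14 slow fibre genes did not differ as a list (median 0.01, mean -0.18, camera adjusted p = 0.676), although myoglobin MB had -0.99 (SE 0.28, adjusted p = 0.288) and MYOZ2 -0.62 (SE 0.22, adjusted p = 0.363). Without Yorkshire replicate 2 the slow fibre list passed, as lower in Shaziling, with an adjusted p of 0.00319, over a range of 0.00319 to 0.891 among its alternatives. The list of myogenic regulators and satellite cells had 9 of 11 genes positive, with a median of 0.30 (camera adjusted p = 0.0236; adjusted p = 0.608 with an estimated correlation) and 0 genes past the threshold over all probe sets or adjusted over the list alone. Its leading members were MSTN and MYF5, a determination factor of muscle cells (1.11, SE 0.42). The camera adjusted p of this list was 0.118 without Yorkshire replicate 2 (median 0.11), 0.0696 without Shaziling replicate 5 and 0.0663 without Shaziling replicate 6 (median 0.18). It was 0.0837 with no filter on dim probe sets (median 0.09), 0.0643 with probe sets Present on at least 1 array, 0.0917 with array weights and 0.0586 with the covariate, over a range of 0.0110 to 0.608 among all alternatives. Without Shaziling replicate 4 the list passed with a median of 0.15.

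Cytosolic ribosomal protein genes were higher in 26 of 27 cases, with a median of 0.17 (camera adjusted p = 1.7e-08; adjusted p = 0.608 with an estimated correlation), 0 of them past the threshold over all probe sets and 0 adjusted over the list alone. RPL30 had 0.40 (SE 0.14), RPL27 0.34 (SE 0.12), RPLP1 0.25 (SE 0.11) and RPL7 0.24 (SE 0.12). The median of the list was 0.07 under quantile normalization (adjusted p = 0.0331) and 0.04 under cyclic loess, where it did not pass (adjusted p = 0.10), over a range of 1.5e-10 to 0.608 among all alternatives. Of 20 heat shock proteins and chaperones, 11 were positive and 9 negative, with a median of 0.11 (camera adjusted p = 0.0233; adjusted p = 0.608 with an estimated correlation); 0 passed over all probe sets and 2 were higher adjusted over the list alone. HSPH1 had 1.47 (SE 0.27, adjusted p = 0.0962), DNAJA1 0.79 (SE 0.18) and HSPB1 1.35 (SE 0.46), against -0.81 (SE 0.26) for DDIT3, a transcription factor of the unfolded protein response. The median of the heat shock list lay at percentile 93.0 of random lists matched on signal. This list did not pass under quantile normalization (median 0.05, adjusted p = 0.0557), cyclic loess (0.03, 0.0721) or with the mean of a gene's probe sets (0.05, 0.0587). Nor did it pass without Yorkshire replicate 2 (adjusted p = 0.0899) or Shaziling replicate 6 (median 0.07, adjusted p = 0.0743), over a range of 0.00191 to 0.608 among all alternatives, and with the covariate its median was 0.27.

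Of 5 immune-related lists, 3 passed as higher in Shaziling, while those of interferon responsive genes and lymphocyte markers did not. Of 12 macrophage and neutrophil markers, 10 were positive, with a median of 0.26 (camera adjusted p = 0.00269; adjusted p = 0.608 with an estimated correlation). LYZ rose past the threshold over all probe sets, and 3 genes were higher adjusted over the list alone. S100A9, a calcium-binding protein of neutrophils, was Present on no Yorkshire array and lay at least 3.79-fold higher in Shaziling, without passing over all probe sets. The Fc receptor FCGR3A had 0.80 (SE 0.24) and AIF1 0.49 (SE 0.32). Of 16 complement and coagulation genes, 12 were positive, with a median of 0.39 (camera adjusted p = 0.000769; adjusted p = 0.608 with an estimated correlation). None passed over all probe sets and 3 were higher adjusted over the list alone, with C4A at 1.48 (SE 0.27, adjusted p = 0.0931), F13A1 at 1.14 (SE 0.27), CD59 at 0.95 (SE 0.24) and CFD at 0.39 (SE 0.21). Of 14 MHC class I and II genes, 11 were positive, with a median of 0.25 (camera adjusted p = 0.0236; adjusted p = 0.737 with an estimated correlation) and 0 past the threshold over all probe sets or adjusted over the list alone. B2M, the class I light chain, had 0.38 (SE 0.20) and the class II chain SLA-DRB1 0.73 (SE 0.40). The macrophage list did not pass without Yorkshire replicate 2 (median 0.13, adjusted p = 0.118), whose mean deviation of -0.72 stood apart, and its median was 0.49 without Shaziling replicate 5. The complement list did not pass without Shaziling replicate 6 (median 0.16, adjusted p = 0.0596), whose mean deviation was 0.63. Their adjusted p-values lay over ranges of 0.000232 to 0.608 and 5.6e-05 to 0.608 among their alternatives. The MHC list did not pass without Yorkshire replicate 1 (0.0691), Yorkshire replicate 2 (0.331, with a median of 0.00) or Shaziling replicate 5 (0.135), nor under quantile normalization (0.0546) or cyclic loess (0.0548), over a range of 0.000232 to 0.737.

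**Figure D3:**
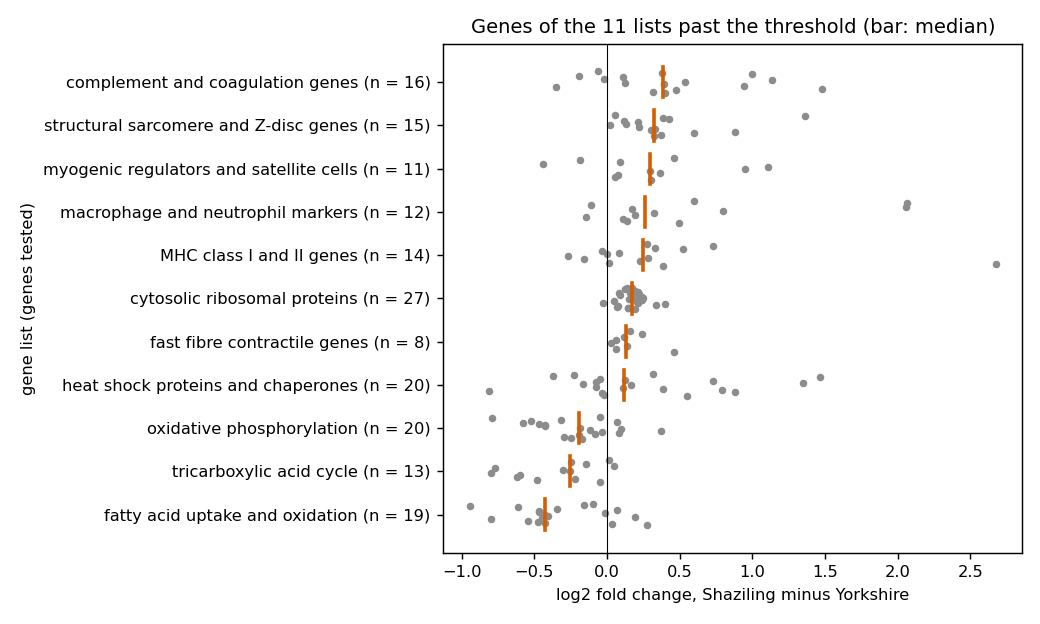
Log2 fold change (Shaziling minus Yorkshire, x axis) of every tested gene (grey points) in the 11 lists past the threshold (y axis, with the number of genes), with the median of each list as an orange bar. The medians range from -0.42 for fatty acid uptake and oxidation to 0.39 for complement and coagulation genes.

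In all, 11 of 33 tested lists passed with camera's preset correlation, 8 higher and 3 lower in Shaziling, and 0 passed with an estimated correlation (smallest adjusted p = 0.608). With fry 1 list passed, that of hypoxia responsive genes (median 0.42 over 6 genes, adjusted p = 0.00217; camera adjusted p = 0.214), led by the collagen hydroxylase P4HA1 at 0.51 (SE 0.20). Its median depended on the filter, at 0.09 with probe sets Present on at least 1 array and -0.15 with no filter (camera adjusted p = 0.611, over a range of 0.00217 to 0.611 among its alternatives).

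Among the tested markers of other cell types, only those of macrophages and neutrophils passed in the main comparison. The median was 0.08 for 10 adipocyte markers (mean -0.23, camera adjusted p = 0.792), with PPARG at -0.99 (SE 0.41). The lipase LIPE, Present on no Shaziling array, had signals that overlapped between breeds (7.54 ± 0.85 in Yorkshire, SD, n = 3). It did not pass (limma adjusted p = 0.340), with a mean at least 4.05-fold lower in Shaziling (log2 fold change -2.02, SE 0.68). For 14 endothelial and pericyte markers the median was -0.06 (mean 0.13, camera adjusted p = 0.395). Among them the von Willebrand factor gene VWF had 2.25 (SE 0.45, limma adjusted p = 0.120) and was the 1 gene higher adjusted over the list alone. CDH5 of the same list had -0.68 (SE 0.29). This list passed as higher in Shaziling with the Present share as a covariate (median 0.40, adjusted p = 0.00497) and without Yorkshire replicate 3 (0.21, adjusted p = 0.0380), over a range of 0.00497 to 0.916, and its median ran from -0.31 to 0.25 when 1 array was left out. The median was 0.35 for 5 lymphocyte markers (adjusted p = 0.255) and -0.22 for 19 collagen and matrix genes (adjusted p = 0.123), led by ASPN at -1.30 (SE 0.41), with 17 of the 19 negative. The collagen list passed as lower without Yorkshire replicate 2 (median -0.58, adjusted p = 0.000215), without Shaziling replicate 6 (-0.41, adjusted p = 9.7e-05), under cyclic loess (adjusted p = 0.0400) and with array weights (adjusted p = 0.0368). Its median was -0.04 without Shaziling replicate 5, and its adjusted p ranged from 9.7e-05 to 0.963 over its alternatives. Genes of fatty acid synthesis had a median of -0.21 (8 genes, adjusted p = 0.676). The lists of fibroblast, blood, nerve, cartilage and epidermal or liver markers had fewer than 5 tested genes and were not tested.

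Other metabolic and regulatory lists that did not pass included 20 antioxidant genes (median -0.26, camera adjusted p = 0.214), of which GSTM3, a glutathione transferase, was lower adjusted over the list alone. It was Present on no Shaziling array and lay at least 3.38-fold lower there (limma adjusted p = 0.114 over all probe sets). In the list of creatine and amino acid metabolism (15 genes, median -0.12, adjusted p = 0.490), 1 gene was higher and 2 were lower adjusted over the list alone. BCKDHB, a subunit of branched-chain ketoacid dehydrogenase, had -1.76 (SE 0.32, adjusted p = 0.0906), the aminotransferase GOT1 -1.01 (SE 0.26) and AMPD1, the muscle AMP deaminase, 0.39 (SE 0.11). Glycolysis had a median of 0.15 (9 genes, adjusted p = 0.162), which was -0.01 without Yorkshire replicate 2 and 0.21 without Shaziling replicate 6. Calcium handling had a median of 0.14 (11 genes, adjusted p = 0.221) and protein breakdown of 0.05 (21 genes, adjusted p = 0.303). Growth hormone and IGF signalling had 0.03 (14 genes, adjusted p = 0.749), imprinted growth genes -0.17 (8 genes, adjusted p = 0.676) and cell cycle genes -0.34 (10 genes, adjusted p = 0.490). Translation factors had 0.11 (14 genes, adjusted p = 0.172), circadian clock genes 0.47 (5 genes, adjusted p = 0.123), immediate early genes -0.43 (8 genes, adjusted p = 0.490), cholesterol synthesis -0.16 (6 genes, adjusted p = 0.490) and interferon responsive genes 0.07 (17 genes, adjusted p = 0.482). Median and mean differed in sign for growth hormone and IGF signalling (0.03 and -0.00), for insulin, AMPK and mTOR signalling (-0.08 and 0.02, adjusted p = 0.529) and for glucocorticoid responsive genes (-0.12 and 0.03, adjusted p = 0.529). The test direction was up for these 3 lists and for the adipocyte and endothelial lists, and down for the slow fibre list. When 1 array was left out or the covariate added, the lists of glycolysis, immediate early, glucocorticoid responsive, circadian clock and calcium handling genes each passed in 1 or 2 fits, with smallest adjusted p-values of 0.0319, 0.0423, 0.0271, 0.0383 and 0.0357 against largest ones of 0.954, 0.943, 0.943, 0.963 and 0.907.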

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

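The fit with the percent of Present calls as a covariate and all tests of Gene Ontology terms were chosen after the data were seen; the other settings were set before. No paired analysis was possible because the breeds share no replicate numbers. The second deposited table holds the same values and so gave nothing to compare, and the robust fit was not run for the lists. Against 31 probe sets past the threshold (14 higher and 17 lower in Shaziling), there were 13 (6 and 7) with no filter on dim probe sets, 19 (6 higher) with probe sets Present on all 6 arrays, 8 (4 and 4) with trend=FALSE, and 364 (132 and 232) with array weights, which ranged from 0.483 for Yorkshire replicate 2 to 3.62 for Yorkshire replicate 1. With other thresholds there were 458 (187 and 271) at an unadjusted p under 0.05 with a 2-fold change, 1499 (631 and 868) at an unadjusted p under 0.05, 61 (28 and 33) at an adjusted p under 0.10 and 0 (0 and 0) at an adjusted p under 0.01 in limma. Leaving out 1 array gave 0 to 27 probe sets, 0 to 14 higher and 0 to 15 lower, and 8 to 13 lists. The cause was not tested, beyond the smaller number of arrays and, for the filters, the different number of probe sets tested. Quantile normalization and cyclic loess each gave 32 probe sets, of which 29 were among the 31, and arrays shifted to the same median gave 35 (19 higher), of which 30 were. Against 11 lists, 0 passed with an estimated correlation and 1 with fry. With the covariate, 36 probe sets passed, 22 of them among the 31, and 9 lists. The 12 named genes kept their side of the threshold in 162 of 236 alternative values and the 11 lists in 171 of 230; none of the called genes or lists passed in the opposite direction. Signal over background limits the dim genes: RNF157 and EEA1 lack a Present call in one breed, and with 64 added to the signal the fold changes of such genes shrink, to -1.84 for RNF157.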

Other observations

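Chosen after the result was seen were the tests of the Gene Ontology terms, of other probe sets of the same transcript and of the 3' to 5' differences. So was the test of the probe sets past the threshold over other splits of the arrays. The single probe sets and genes named here were also chosen then, apart from genes that the rule had already named, such as FABP4. Genes annotated to the mitochondrion passed as a group with lower mRNA signals in Shaziling with camera's preset correlation, but not with an estimated one. Of 134 tested genes with this term, 95 had negative fold changes, 22 of them at an unadjusted p under 0.05 against 3 positive ones, with a median of -0.20 (camera adjusted p = 0.00011 over 169 terms; adjusted p = 0.978 with an estimated correlation). No single gene passed over all probe sets. Leaving out the genes of the 3 mitochondrial lists left 100, of which 69 were negative, with a median of -0.16 against -0.06 over all genes, and these 100 were not tested on their own. They included MUT, the methylmalonyl-CoA mutase (log2 fold change -1.32, SE 0.27, limma adjusted p = 0.128), glutathione reductase GSR (-0.82, SE 0.22), the deacetylase SIRT3 (-0.85, SE 0.25) and OXCT1 of ketone body use (-0.60, SE 0.21). In all, 8 terms passed, 5 higher in Shaziling and 3 lower, and 0 passed with an estimated correlation.

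Several signals stood out without passing the threshold. A probe set titled as similar to myosin-8, the perinatal myosin, had a log2 fold change of 1.53 (SE 0.24, limma adjusted p = 0.0510), while another probe set with that title had -0.19 (SE 0.27). A probe set without a gene name had a log2 signal of 9.07 ± 0.58 in Shaziling (SD, n = 3), Present on all 3 arrays, and was Present on 1 Yorkshire array, where the mean signal of 3.60 lay near background, so that its fold is not known (limma adjusted p = 0.0931). A probe set annotated as FABP4, an adipocyte fatty acid carrier, and another annotated as CD74, the MHC class II invariant chain, share a transcript cluster in their identifiers. They had log2 fold changes of 2.52 (SE 0.84, limma adjusted p = 0.338) and 2.68 (SE 0.91, limma adjusted p = 0.340). The other, brighter FABP4 probe set had 0.47 (SE 0.25, limma adjusted p = 0.552).

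With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The breed split gave 31 probe sets past the threshold, in 1 of the 10 splits as many, with 0 as the highest of the others. It gave 11 lists, and 4 of the 10 splits gave as many, with 15 as the highest of the others. For Gene Ontology terms it gave 8, and 2 of the 10 splits gave as many, with 9 as the highest of the others.

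Of 7 called probe sets with other tested probe sets of the same gene or transcript cluster, MARCH6 and an unnamed one (2 of the 7) had none whose 95% interval reached the midpoint between no change and the called shift. This argues against a difference in the level of the whole transcript for these 2, and a sequence variant under the probes or an alternative 3' end may account for them, which was not tested. EEA1 stays open: its 3 other probe sets did not reach that midpoint, but 1 unnamed probe set described as similar to the same protein and placed on chromosome 10 rose with it (log2 fold change 2.99, SE 0.33, limma adjusted p = 0.0176). For the other 4, HUS1, the SATB1-like and isobutyryl-CoA dehydrogenase-like probe sets and an unnamed one, every other tested probe set moved the same way, with -0.89 (SE 0.32) beside -2.64 for HUS1. A difference of the whole transcript stays open for these 4, since they were grouped by that very result.

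The small upward shift of ribosomal protein genes sits at the top of the signal range (median log2 signal 14.53), where signal-matched genes also lay above 0 (median 0.11). The list's median of 0.17 was at the 99.3th percentile of random lists matched on signal, past the limit written beforehand for setting a signal trend aside. That limit was dropped after the result was seen, since random lists treat genes as independent while the estimated correlation within the list was 0.19. Cyclic loess, which removes a trend with the level, took the median from 0.17 to 0.04 and ended the call (adjusted p = 0.10, over a range of 1.5e-10 to 0.608 among all alternatives). A trend with the signal level may thus account for much of the shift and cannot be told apart from a change in ribosomal genes, since the random lists ignore that correlation. Variation shared by these genes between animals was tested by the mean moderated t: it was 1.64 for breed, with 1 of 10 splits as large and 0.98 as the highest of the others, too few splits for a share under 0.05.

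A split that cuts across breed, with Yorkshire replicates 1 and 3 and Shaziling replicate 4 against the other 3 arrays, gave 1909 probe sets at an unadjusted p under 0.05, against 1499 for breed, and 0 past the threshold. It was the largest of the 9 splits other than breed. The first principal component, the axis of largest variation (33.1%), parted the arrays the same way. It was -20.08, -45.95 and -13.96 on the former arrays, in the order given. On Yorkshire replicate 2 and Shaziling replicates 5 and 6 it was 4.15, 49.17 and 26.67. Lists picked after their values were seen also followed this split. Mean deviations of antioxidant and cell cycle genes were higher on the former arrays, those of insulin, AMPK and mTOR signalling lower. The former 3 arrays had 59.9% to 60.6% Present calls and the latter 56.3% to 58.2%. Lower detection sensitivity was predicted beforehand to part dim probe sets most. The share under 0.05 was instead 10.8% among the 7206 dimmer probe sets and 15.7% among the 7207 brighter ones. By the rule written beforehand this counted against lower sensitivity. That reading was set aside, since the spread of MAS5 signals depends on the level and the share cannot decide. The median shift, former minus latter arrays, was larger among the dimmer probe sets (0.016 against 0.007 on the log2 scale). Its size was larger among them in every other split too, such as breed (0.068 against 0.009, Yorkshire minus Shaziling), so it decides nothing. Lower sensitivity therefore stays open. The difference of -4.92 points was the lowest of the 10 splits, against -2.45 for breed and -0.62 to 1.01 for the others. RNA degradation stays open, as the sides overlapped in both measures (2 of 2), the 3' to 5' differences of actin and of GAPDH, which 3 arrays against 3 often do. Sibling differences in muscle state or in sampling stay open too and were not tested.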
